A study of Gallus gallus with 20 samples.

How the data were processed

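RNA from whole macerated chicken embryos was sequenced at 1, 2, 3, 5 and 7 days after infection with infectious bursal disease virus, and from uninfected embryos at the same days, with 2 libraries in each of the 10 groups. Per the labels, RNA was taken with a TRIzol-based kit and made into strand-specific mRNA libraries with a SureSelect kit. The deposited raw table holds whole-number counts per gene for each of the 20 libraries, and these counts were the only values tested. Per the submitters' processing notes the tools used were FastQC, Trimmomatic, HISAT2, featureCounts and DESeq, with no versions or settings. The deposited normalized table holds a signal that equals the raw count divided by 1 size factor per library. That factor was recomputed here as the median of ratios over 13941 genes, with a gap below 1e-09. The genome build and annotation used by the authors are not given in the sources used here, so no coordinates are reported.

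The count table had 20264 lines with 19900 different gene IDs, and 1693 lines had no count in any library. A total of 153 IDs stood on more than 1 line (517 lines), and these lines were kept apart. IDs were looked up in a current table of chicken genes: 14714 matched by symbol, 502 by gene number and 373 by synonym, which makes 15589, and 4311 matched nothing. Chromosomes and second names come from that table. Genes carry the name given in the count table. For a few, the current table has another name: S100A9 is S100A12, IFI27L2 is ISG12-2, HNRPK is HNRNPKL, HBG1 is HBBR, SERPINA4 is SPIA4 and HSP25 is HSPB9. Counts of near-identical copies are uncertain, since the authors' rule for shared reads is unknown. This applies to BF1 and BF2, to the keratin families and to the fast myosins.

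Each library is named by its group and its total in M counts (M, mega), because the columns carry no replicate numbers. Totals ran from 2.78 to 60.7 M with a median of 6.61 M. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr on the 10 groups, and quasi-likelihood F tests with 1 mean per group over all 20 libraries, which left 15122 genes and 10 residual degrees of freedom. The common dispersion was 0.0575, a biological coefficient of variation of 0.24. Infected and uninfected embryos were compared on each day and averaged over the 5 days. An F test asked whether the 5 daily differences were equal, and uninfected day 7 was compared with uninfected day 1. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The error of a log2 fold change is its size divided by the square root of F. Errors of values computed from list medians come from resampling genes, and leave out the spread between libraries. CPM (counts scaled to a common library total) use TMM-scaled totals and are given as mean ± SD with n = 2 per group; for W-linked genes they use plain totals. Log2 CPM in list tests carry a prior count of 2, and fitted fold changes edgeR's default prior. Where all libraries of a group had no count, the fold is given as a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with a 95% counting interval. Intervals and bounds cover counting error only. Nothing in the labels says how many embryos a library holds, or that libraries came from separate embryos, so the p values measure the spread between libraries.

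A set of 28 gene lists (pathways, cell type markers and checks of library make-up) was tested with camera from limma 3.58.1 at a preset correlation of 0.01. The p values were adjusted over all lists and the 6 infection comparisons together, and apart from these for the comparison of ages. Estimated correlations were the alternative. For each list the number of members past the test over all genes is given with the number adjusted over the list alone. A list of 13 mitochondrially encoded genes matched 0 lines and could not be tested.

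The groups, comparisons, tests, lists, named genes and alternatives were fixed before the data were examined. In each comparison the named genes are the 10 largest rises and 10 largest falls by log2 fold change among genes past the threshold with a mean log2 CPM of at least 0, a proper symbol, and both infected libraries on the same side of both uninfected ones. For the average, the sign had to be the same in at least 4 of 5 days, and for the test among days the 10 smallest p values count. Where fewer than 5 genes passed, the 5 smallest p values are named as not passing. Up to 4 members of each list with the smallest p and a fixed set of immune genes (among them MX1, IFIT5, OASL, RSAD2, IRF7, IL6, CD79B and PTPRC) are added where measured. Some genes that this rule names are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

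The alternatives were median-of-ratios scaling, no low-count filter, DESeq2 1.42.0 (Wald tests, and a likelihood ratio test among days), each library left out in turn, only the libraries of the day, and estimated correlations for lists. Added after seeing the data were W-linked expression (log2 CPM of HNRPK) as a covariate, all libraries thinned at random to 2.78 M counts, an average over days 3, 5 and 7, and differences between daily effects. With 1 mean per group, the slope of the W-linked covariate comes only from groups whose 2 libraries differ in HNRPK. The edgeR comparisons and camera were tested on simulated counts with 2-, 4- and 8-fold changes of known genes; the alternatives, the reassignments and the differences between days were not. The changed genes of the edgeR comparisons had a mean log2 CPM of at least 0, and each gene had the same spread in every group. In the comparison at day 7 (14977 genes) 37.3% of the 2-fold, 82.1% of the 4-fold and 87.9% of the 8-fold changes were called. The shares at day 1 were 22.4%, 70.1% and 86.4%, at day 2 31.3%, 71.6% and 83.3%, at day 3 34.3%, 67.2% and 86.4%, and at day 5 32.8%, 74.6% and 74.2%. They were 71.6%, 91% and 100% for the average (14987 genes), 4.5%, 55.2% and 66.7% for the test among days (14968 genes), and 34.3%, 77.6% and 81.8% for the change with age (14889 genes). Unchanged genes made up 9 of 147 calls at day 7, 11 of 186 for the average, 6 of 90 among days and 4 of 133 with age. On days 1, 2, 3 and 5 they made up 4 of 123, 1 of 125, 3 of 128 and 5 of 126. No deposited value column was left out.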

Results

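Gene expression was measured in whole macerated chicken embryos after infection with infectious bursal disease virus, a birnavirus with a double-stranded RNA genome, and in uninfected embryos of the same days. There were 2 infected and 2 uninfected libraries on each of days 1, 2, 3, 5 and 7 after infection. Totals ran from 2.78 to 60.7 M counts (M, mega). The infected pairs held 3.54 and 9.6 M at day 1, 9.84 and 5.1 M at day 2, 6 and 2.78 M at day 3, 10.04 and 6.58 M at day 5, and 60.7 and 4.25 M at day 7. The uninfected pairs held 6.71 and 6.65, 9.35 and 6.12, 5.96 and 5.54, 7.34 and 8.02, and 6.55 and 8.76 M on the same days. Libraries of 1 group correlated at 0.912 to 0.971 across genes (log2 CPM, Pearson), which are not independent replicates. The infected pair of day 7 was lowest, and the other groups had 0.953 to 0.971. The first principal component took 40% of the variance and the second 11.9%.

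W-linked genes, carried by the chromosome that only female birds have, were not balanced between the groups. HNRPK, the W-linked gene with most counts, stood at 87.9 and 117 CPM in the infected libraries of day 3 and at 0.503 and 0.18 CPM in the uninfected ones. At day 5 the order was the opposite, with 0.199 and 0.304 CPM in infected and 112 and 248 CPM in uninfected libraries. At day 7 the infected libraries of 60.7 and 4.25 M counts had 155 and 0.47 CPM. The uninfected libraries of 6.55 and 8.76 M had 8.7 and 0.228 CPM. At day 1 the infected values were 0.565 and 133 CPM and at day 2 0.305 and 252 CPM, while the uninfected libraries had 118 and 148, and 255 and 142 CPM. None of the 5 W-linked genes passed edgeR's quasi-likelihood test over all genes on any day, while all 5 were lower at day 5 adjusted over the list alone (0 on the other days). As a list they had a median log2 fold change of -0.67 at day 1 (adjusted p = 0.0343 by camera, 0.813 with an estimated correlation), of -1.23 at day 2 (0.00176, and 0.516 with an estimated correlation), of 8.14 at day 3 (adjusted p = 0.0025 by camera, 0.534 with an estimated correlation) and of -8.26 at day 5 (3.88e-05, and adjusted p = 0.279 with an estimated correlation). With undetected genes at their bound the medians of days 3 and 5 were 4.13 and -5.93.

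**Figure D1:**
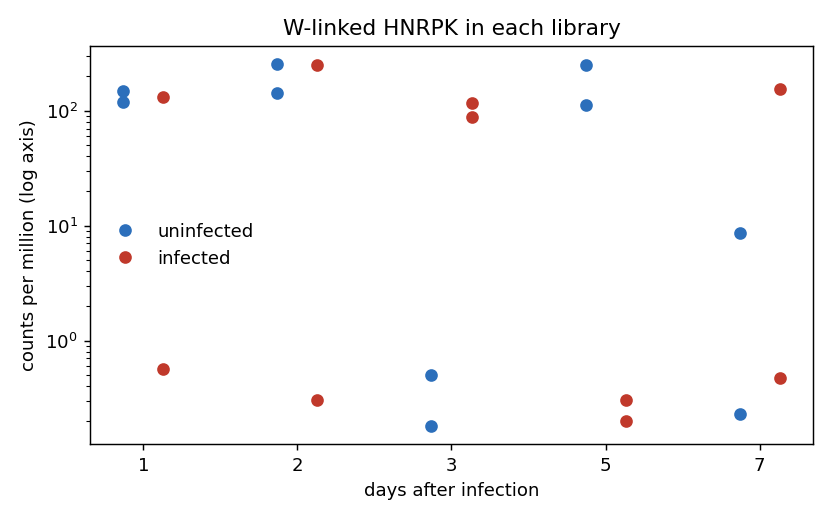
CPM (counts scaled to a common library total, log axis) of the W-linked gene HNRPK in each of the 20 libraries by day and group, with 1 point per library. It lay at 87.9 and 117 CPM in the infected libraries of day 3 against 0.503 and 0.18 in the uninfected ones, and the order was the opposite at day 5.

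The first comparison asked how infection changed the embryos at day 1, and no gene passed the test. The smallest p values belonged to MYH11, the smooth muscle myosin, at a log2 fold change of -1.77 ± 0.32 (SE), and to UPK3A, a protein of the urinary tract lining, at -3.03 ± 0.69. MUC16, an epithelial mucin, had a ratio of 15.2 lower in the infected embryos (95% counting interval 3.88 to 131). None passed edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.887). The 48 interferon-stimulated genes, which infected cells switch on under interferon, had a median log2 fold change of -0.05 and a mean of -0.02, while camera gave the opposite sign (adjusted p = 0.987). Of the other lists, camera placed the 32 skin and feather markers lower (median -0.41, adjusted p = 0.00176, and adjusted p = 0.933 with an estimated correlation), with 0 members past the gene test by either adjustment. edgeR called 0 genes and DESeq2 2, both lower. Of 15122 genes 166 had an unadjusted p under 0.05, below the share of 0.05 that no difference at all would give. The spread was estimated over all groups and may be too large for day 1. So low a share therefore does not show that infection had no effect. In simulated data 22.4% of 2-fold and 70.1% of 4-fold changes were called at day 1, so smaller changes could be missed. The simulation gave each gene the same spread in every group, so it leaves out such an excess of spread.

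At day 2, again, no gene passed. MYL12A, a myosin light chain, was at -1.78 ± 0.33 and S100A9, a calcium-binding protein of granulocytes, at 1.39 ± 0.26 (both adjusted p = 0.677, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). SLC25A34, a mitochondrial carrier, stood at 2.05 ± 0.51 and did not pass either. The interferon-stimulated genes had a median of -0.02 (adjusted p = 0.46 by camera). Camera placed the 24 erythroid markers higher (median 0.31, adjusted p = 0.00264, and adjusted p = 0.666 with an estimated correlation) and the 34 skeletal muscle markers lower (median -0.2, adjusted p = 0.0416, and adjusted p = 0.995 with an estimated correlation), both with 0 members past the gene test by either adjustment. edgeR called 0 genes and DESeq2 1. An unadjusted p under 0.05 was seen for 187 of 15122 genes, again below the share of 0.05 that no difference would give. As at day 1, the shared spread may be too large, so this does not show that infection had no effect. In simulated data of these libraries 71.6% of 4-fold changes were called at day 2, so smaller changes could be missed at this depth.

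At day 3 interferon-stimulated genes rose strongly in the infected embryos. OASL, an antiviral oligoadenylate synthetase-like protein, rose from 4.54 ± 0.033 to 2510 ± 1590 CPM (mean ± SD, n = 2), a log2 fold change of 9.11 ± 0.67 (adjusted p = 4.28e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). RSAD2 (viperin), which blocks the replication of many viruses, rose by 10.81 ± 0.73 from 0.347 ± 0.491 to 641 ± 433 CPM. MX1, an antiviral GTPase, rose by 10.45 ± 1.05 from 0.345 ± 0.249 to 501 ± 521 CPM. IFIT5, which binds viral RNA, was higher by a ratio of 4530 (95% counting interval 1250 to 37400). In all, 117 genes rose and 1 fell. The fall was ANKRD33B, at least 6.61-fold lower with no count in the infected libraries, a call that no fit with 1 of the 4 libraries left out kept.

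Of the 48 interferon-stimulated genes, 38 rose at day 3 and 10 did not pass (42 rose adjusted over the list alone), with a median log2 fold change of 3.88. The list stood above other genes by camera (adjusted p = 6.77e-116, and adjusted p = 0.0122 with an estimated correlation). Of 28 genes of virus sensing and interferon induction, 10 rose (11 adjusted over the list alone; median 0.48, adjusted p = 6.48e-24, and adjusted p = 0.019 with an estimated correlation), 2 of them outside the interferon-stimulated list. IFIH1 (MDA5) and TLR3, sensors of double-stranded RNA, rose by 5.47 ± 0.46 and 5.14 ± 0.6. The transcription factors IRF7 and IRF1, which drive interferon genes, rose by 4.76 ± 0.4 and 5.07 ± 0.45. Of 17 genes of interferon signalling, 3 rose (5 adjusted over the list alone; adjusted p = 3.71e-08, and adjusted p = 0.0304 with an estimated correlation). Among them were STAT2 (2.84 ± 0.27) and SOCS1, a brake on that pathway (3.51 ± 0.45).

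Antigen presentation also rose at day 3, with 8 of 23 genes higher (12 higher and 1 lower adjusted over the list alone; median 0.89, adjusted p = 7.23e-11, and adjusted p = 0.0439 with an estimated correlation). B2M, the light chain of class I molecules, rose by 3.52 ± 0.46. Of 35 complement and acute phase genes 3 rose (4 adjusted over the list alone), among them the complement protease C1S (3.54 ± 0.41). The list had a median of 1.05 (adjusted p = 1.6e-07, and adjusted p = 0.723 with an estimated correlation). S100A9 rose by 3.37 ± 0.26, from 7.96 ± 0.209 to 82.1 ± 12.9 CPM, as the 1 member called among 25 antimicrobial and granulocyte genes (2 adjusted over the list alone; median 0.88, adjusted p = 3.66e-06, and adjusted p = 0.384 with an estimated correlation). Of 34 cell death genes 2 rose (4 adjusted over the list alone; adjusted p = 6.73e-05, and adjusted p = 0.149 with an estimated correlation). No member of the 23 cytokines and chemokines passed (1 adjusted over the list alone; median 0.24, adjusted p = 0.00103, and adjusted p = 0.0604 with an estimated correlation). Camera also placed 27 macrophage markers (median 0.12, adjusted p = 0.0209), 21 pan-leukocyte markers (median 0.27, adjusted p = 0.0062) and 22 immediate early genes (median 0.25, adjusted p = 0.0423) higher, with 0 members called (3, 0 and 0 adjusted over the list alone). With an estimated correlation these 3 lists had adjusted p = 0.928, 0.78 and 0.928. PTPRC (CD45), carried by all leukocytes, was at 1.69 ± 0.55 and did not pass (adjusted p = 0.434, edgeR's quasi-likelihood test).

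The count of 118 genes at day 3 became 194 without the infected library of 6 M counts, 68 without that of 2.78 M, and 59 and 55 without the uninfected libraries of 5.96 and 5.54 M. Without the infected library of 2.78 M and the uninfected ones of 5.96 and 5.54 M in turn, 32, 32 and 29 of the 38 interferon-stimulated rises kept their call, and 8, 8 and 7 of 10 in virus sensing. In antigen presentation 3, 1 and 2 of 8 did, in complement and acute phase 1 each of 3, and in cell death 0 each of 2. DESeq2 called 187 genes, and 68 were called with W-linked expression as a covariate, all of them among the 118 and 33 of them interferon-stimulated. All 117 rises kept their sign. Their median was 3.31 (median SE 0.46) without the covariate and 3.16 (median SE 0.55) with it. The calls thus ended with a wider error. The slope of the covariate came mostly from pairs of other days, so these folds do not decide on sex at day 3.

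**Figure D2:**
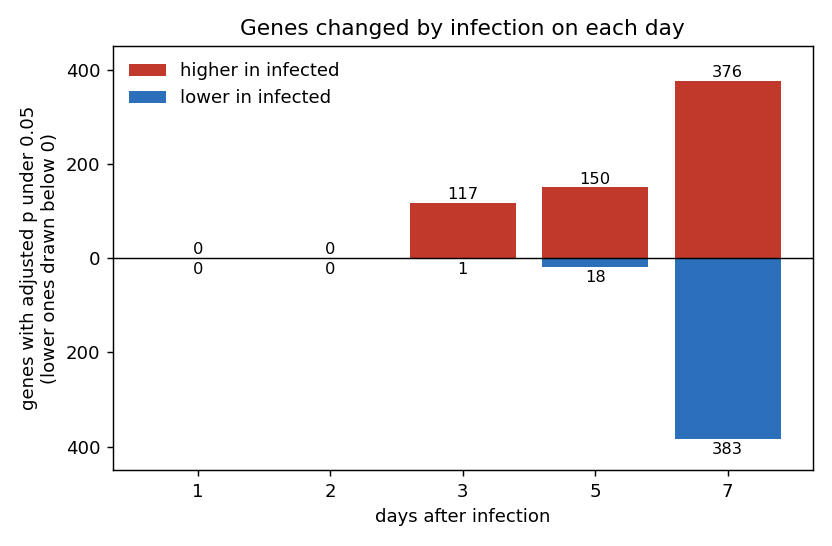
Number of genes higher (above 0) and lower (below 0) in infected than in uninfected embryos on each day, by edgeR's quasi-likelihood test at an adjusted p under 0.05, 2 libraries per group. The bars grow from 0 at days 1 and 2 to 117 higher and 1 lower at day 3, 150 and 18 at day 5, and 376 and 383 at day 7.

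At day 5, 150 genes rose and 18 fell. OASL stood at 2420 ± 73.1 against 2.99 ± 0.774 CPM (log2 fold change 9.66 ± 0.69, adjusted p = 5.83e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). IFIT5 rose by 10.35 ± 0.78, MX1 by 10.04 ± 0.98, IFI6 by 9.63 ± 0.82 and RSAD2 by 8.85 ± 0.65. AVD (avidin), a biotin-binding egg white protein, rose by 6.96 ± 0.96. LY86 (MD-1), a partner of Toll-like receptor relatives on B cells and macrophages, fell by 3.32 on the log2 scale (SE 0.44).

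The interferon-stimulated list had 37 of 48 members higher at day 5 (42 adjusted over the list alone; median 3.81, adjusted p = 3.06e-87 by camera, and adjusted p = 0.0131 with an estimated correlation). Virus sensing had 9 of 28 higher (14 adjusted over the list alone; adjusted p = 7.29e-17, and adjusted p = 0.0304 with an estimated correlation), 1 of them outside the interferon-stimulated list, with IRF1 at 5.63 and IFIH1 at 4.37. Of the 17 interferon signalling genes 3 rose (5 adjusted over the list alone; adjusted p = 3.41e-05, and adjusted p = 0.0636 with an estimated correlation). In antigen presentation 7 of 23 rose (11 higher and 1 lower adjusted over the list alone; median 1.24, adjusted p = 3.61e-11, and adjusted p = 0.0439 with an estimated correlation), with the class I heavy chain BF2 at 5.31 ± 0.61 and B2M at 4.17 ± 0.46. Complement and acute phase genes had 5 of 35 higher (11 adjusted over the list alone; median 1.08, adjusted p = 1.26e-09, and adjusted p = 0.554 with an estimated correlation), with C1S at 4.27 ± 0.41. Of 34 cell death genes 3 rose (7 adjusted over the list alone; adjusted p = 0.00259, and adjusted p = 0.337 with an estimated correlation). None of the cytokines and chemokines passed (0 adjusted over the list alone; median 0.39, adjusted p = 0.0206, and adjusted p = 0.19 with an estimated correlation).

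Blood cell lists also moved by camera at day 5. Of the 24 erythroid markers 2 rose (7 adjusted over the list alone), H1F0, a linker histone, at 1.52 ± 0.28 and LMO2, a blood transcription factor, at 1 ± 0.21. The list had a median of 0.47 (adjusted p = 0.00911, and adjusted p = 0.78 with an estimated correlation). H1F0 and LMO2 each missed the threshold without any 1 of the 4 libraries of the day, at 1.46 to 1.57 and 0.91 to 1.08. Among 27 macrophage markers LY86 and TIMD4, a receptor for dying cells (-1.77 ± 0.38), fell, while 2 higher and 2 lower passed adjusted over the list alone. The list had a median of -0.43 (adjusted p = 0.0215, and adjusted p = 0.928 with an estimated correlation). The 21 pan-leukocyte markers had 0 members called (1 lower adjusted over the list alone) and a median of -0.24 (adjusted p = 0.0118, and adjusted p = 0.813 with an estimated correlation). Liver markers had a median of 0.44 (adjusted p = 0.046, and adjusted p = 0.995 with an estimated correlation) with 1 of 39 higher by both adjustments, FABP1, a fatty acid carrier, at 3.79 ± 0.6. Of the 14 thrombocyte and 17 eye markers 1 each fell (2 higher and 1 lower, and 2 lower, adjusted over the list alone), F13A1, a clotting factor subunit, at -1.8 ± 0.4, and PMEL, a pigment cell protein, at -2.68 ± 0.5. Cholesterol and fatty acid synthesis (median 0.32, adjusted p = 0.00526, and adjusted p = 0.149 with an estimated correlation) and immediate early genes (median 0.29, adjusted p = 0.0118, and adjusted p = 0.78 with an estimated correlation) had 0 members called (1 higher and 0 adjusted over the list alone). TIMD4 missed the threshold without the infected libraries of 10.04 (-1.84) and 6.58 M counts (-1.73) and without the uninfected one of 8.02 M (-1.4). FABP1 missed it without the uninfected libraries of 7.34 (4.07) and 8.02 M (3.54), PMEL without that of 7.34 M (-1.59) and both infected ones (-3.21 and -2.34), and F13A1 without any 1 of the 4 (-2.05 to -1.51).

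The 168 genes of day 5 became 91 without the infected library of 10.04 M counts, and 87 and 61 without the uninfected libraries of 7.34 and 8.02 M. The 18 falls became 3 and 4 without the infected libraries of 10.04 and 6.58 M, and 8 and 3 without the uninfected ones of 7.34 and 8.02 M. Without the infected library of 10.04 M and the uninfected ones of 7.34 and 8.02 M in turn, 34, 32 and 28 of the 37 interferon-stimulated rises kept their call, and 7, 5 and 2 of 7 in antigen presentation. In complement and acute phase 3, 2 and 1 of 5 did, and in cell death 0 each of 3. DESeq2 called 283 genes (227 higher, 56 lower) and the 4 libraries of the day alone gave 229 (198 higher, 31 lower). With W-linked expression as a covariate 108 were called (104 higher, 4 lower; 97 of them among the 168); the median of the 150 rises was 3.03 (median SE 0.44) without it and 3.23 (median SE 0.56) with it, and that of the 18 falls -1.47 (0.32) and -1.22 (0.39). With all libraries thinned to 2.78 M 88 were called (85 higher, 3 lower).

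**Figure D3:**
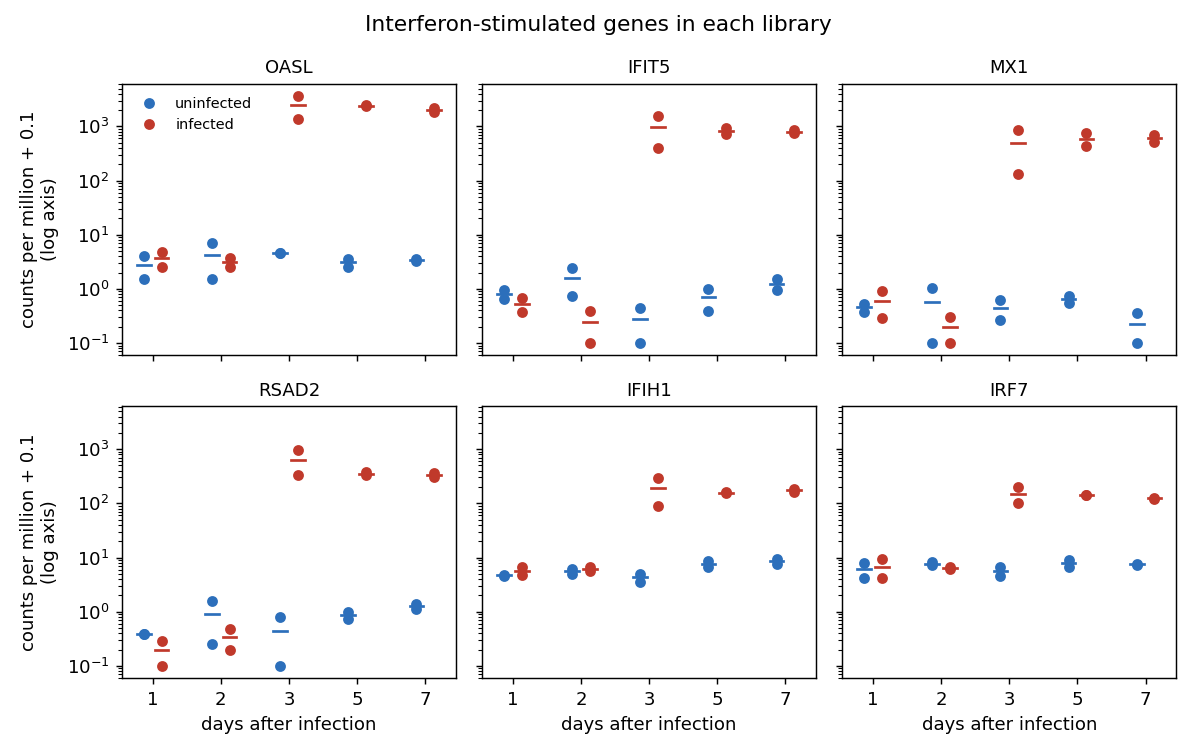
CPM plus 0.1 (log axis) of OASL, IFIT5, MX1, RSAD2, IFIH1 and IRF7 in infected and uninfected embryos by day after infection, with 1 point per library and a short line at the group mean. None of the 6 genes passed the test at days 1 and 2, and at day 3 OASL stands at a mean of 2510 CPM in infected against 4.54 in uninfected embryos.

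At day 7, 376 genes were higher and 383 lower. This was more than on the other days when the spread was taken from all 20 libraries, but not with only the 4 libraries of each day, which gave 64 genes at day 7 against 137 at day 3 and 229 at day 5. Interferon-stimulated genes were still higher: OASL stood at 1990 ± 228 against 3.29 ± 0.251 CPM (log2 fold change 9.23 ± 0.68, adjusted p = 6.01e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and MX1 was higher by a ratio of 3860 (95% counting interval 1070 to 31900). The largest falls included genes of plasma proteins. HRG, a plasma glycoprotein, went from 490 ± 122 to 20.7 ± 2.8 CPM (-4.59 ± 0.36) and SPP2 from 1010 ± 88.2 to 27.4 ± 4.61 CPM (-5.22 ± 0.45). The protease inhibitors SERPINA5 and SERPINA4 changed by -5.66 ± 0.79 and -4.45 ± 0.47, the former by -12.33 without the infected library of 60.7 M counts.

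At day 7, 39 of the 48 interferon-stimulated genes rose, 1 fell and 8 did not pass (42 higher and 1 lower adjusted over the list alone; median 3.43, adjusted p = 7.46e-47 by camera, and adjusted p = 0.0343 with an estimated correlation). The fall was LAP3, an aminopeptidase (-0.72), named after its value was seen, whose call was lost without the infected library of 4.25 M counts (-0.6) and without the uninfected ones of 6.55 and 8.76 M (-0.59 and -0.81). Virus sensing had 12 of 28 higher (14 adjusted over the list alone; adjusted p = 1.53e-10, and adjusted p = 0.0679 with an estimated correlation), with ZNFX1 at 5.12 and IFIH1 at 4.38. Of the 17 interferon signalling genes 5 rose (7 adjusted over the list alone; adjusted p = 5.03e-06, and adjusted p = 0.0442 with an estimated correlation), with STAT2 at 2.55. Antigen presentation had 13 of 23 higher (16 adjusted over the list alone; median 1.99, adjusted p = 1.39e-10, and adjusted p = 0.0439 with an estimated correlation), 11 of them outside the interferon-stimulated list, with BF2 at 4.75 ± 0.59 and B2M at 4.04 ± 0.45. Of 34 cell death genes 4 rose (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.00322, and adjusted p = 0.351 with an estimated correlation), among them BIRC2, an inhibitor of apoptosis, at 1.48. Of the cytokines and chemokines 1 of 23 rose (2 adjusted over the list alone; median 1.17, adjusted p = 0.00579, and adjusted p = 0.114 with an estimated correlation). The gene was CX3CL1 (1.29 ± 0.35), whose call was lost without any 1 of the 4 libraries of the day (0.94 to 1.75).

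Of 39 liver markers 11 fell, 0 rose and 28 did not pass (17 lower adjusted over the list alone), with a median of -1.05. Camera placed the list lower (adjusted p = 2.48e-12), but not with an estimated correlation (adjusted p = 0.554). GC, the vitamin D carrier of plasma, stood at 265 ± 212 against 2710 ± 666 CPM (-3.35 ± 0.57), FBP1, an enzyme of glucose synthesis, at 167 ± 122 against 1040 ± 116 CPM (-2.62 ± 0.42), and TTR, the thyroid hormone carrier, at -3.57 ± 0.62 (-5.56 without the infected library of 60.7 M counts). The infected libraries differed in these genes. The median change of 36 liver markers against the uninfected mean was -0.52 in the library of 60.7 M counts (range -3.13 to 2.77) and -4.04 in that of 4.25 M (range -7.36 to -0.06). Without the 60.7 M library the list median was -3.93 with 29 markers lower (adjusted p = 2.38e-42, and adjusted p = 0.0198 with an estimated correlation). Without the 4.25 M library it was -0.6, with 7 markers higher and 11 lower (adjusted p = 0.0213, and adjusted p = 0.786 with an estimated correlation). Without the uninfected libraries of 6.55 and 8.76 M it was -1.3 with 5 lower and -1.2 with 8 lower.

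**Figure D4:**
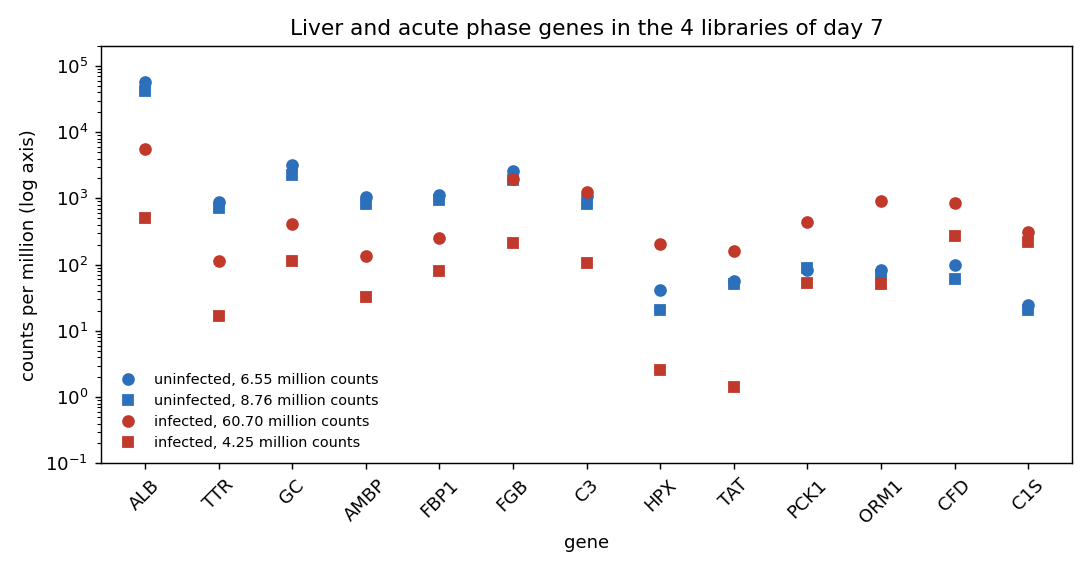
CPM (log axis) of liver and acute phase genes in the 4 libraries of day 7, with 1 point per library; infected libraries are marked by their totals of 60.7 and 4.25 M counts, and the genes were chosen after their values were seen. ALB stands at 5580 and 501 CPM in the infected libraries against 56300 and 42500 in the uninfected ones, while HPX stands at 202 and 2.59 against 41.3 and 20.8.

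Of 25 antimicrobial and granulocyte genes 7 fell at day 7 and 0 rose (9 lower and 1 higher adjusted over the list alone; median -0.69, adjusted p = 8.93e-05, and adjusted p = 0.535 with an estimated correlation). AvBD1, a beta-defensin, changed by -4.42 ± 0.63, LECT2, a liver-made chemotactic factor, by -4.31 ± 0.69 and LEAP2, a liver-made peptide, by -3.7 ± 0.67. The infected libraries stood apart for these genes too, which went to -10.72, -6.49 and -10.15 without that of 60.7 M counts and to -3.9, -3.74 and -3.16 without that of 4.25 M. Complement and acute phase genes split, with 6 of 35 higher and 5 lower (9 and 9 adjusted over the list alone). C1S rose by 3.55 ± 0.4 and complement factor D (CFD) by 2.82 ± 0.43 (1.75 without the library of 60.7 M), while AMBP, a plasma protease inhibitor, changed by -3.45 ± 0.5. The median of this list was -0.12, its mean 0.02, and camera gave the negative sign (adjusted p = 0.138). Among 27 macrophage markers 5 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.752), and the falls were LY86 (-2.91 ± 0.4) and TIMD4 (-2.3 ± 0.37). Both falls were kept with each library left out, but of the 5 rises 0 kept their call without the infected library of 60.7 M, 0 and 1 without the uninfected ones of 6.55 and 8.76 M, and 5 without the infected one of 4.25 M. Of 31 genes of glycolysis and the hypoxia response 3 rose and 4 fell (11 and 10 adjusted over the list alone), with LDHB, a lactate dehydrogenase, at -2.57 ± 0.29 (adjusted p = 0.000102, edgeR's quasi-likelihood test). That list had a median of 0.4, while camera gave the negative sign (adjusted p = 0.977). Of 22 immediate early genes 3 rose (9 adjusted over the list alone; median 0.79, adjusted p = 7.34e-05, and adjusted p = 0.39 with an estimated correlation). These were FOS (1.94), ATF3 (1.81) and KLF6 (0.86), which went to 0.64, 0.72 and 0.51 and lost their calls without the infected library of 60.7 M; the calls were also lost without the uninfected ones of 6.55 M (2.61, 1.74 and 0.96) and 8.76 M (1.5, 1.94 and 0.81). Of 32 genes of cholesterol and fatty acid synthesis 2 rose (6 adjusted over the list alone; median 0.41, adjusted p = 0.00249, and adjusted p = 0.114 with an estimated correlation). The 34 skeletal muscle markers had 0 members called by either adjustment and a median of -0.27 (adjusted p = 0.0326, and adjusted p = 0.995 with an estimated correlation).

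Other tissue lists showed few calls at day 7. SI (sucrase-isomaltase), a digestive enzyme of the gut lining, rose by 3.99 ± 0.48, and 2 of 33 kidney, lung and gut markers rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.443 by camera). Of 32 skin and feather markers 2 rose (2 adjusted over the list alone; adjusted p = 0.109), and 1 each of 22 heart (1 adjusted over the list alone; adjusted p = 0.953) and 37 cartilage and bone markers rose (0 adjusted over the list alone; adjusted p = 0.198). The calls of the heart gene, NPPB (2.61), and of the bone gene, SPP1 (3.05), both named after their values were seen, were lost without the infected library of 60.7 M counts (0.22 and -0.13) and without the uninfected ones of 6.55 M (3 and 3.38) and 8.76 M (2.34 and 2.8). The same 3 libraries each took both skin calls and 1 of the 2 rises among kidney, lung and gut markers, while that of SI was kept, and the fall of the latter list was lost without those of 60.7 and 8.76 M. Heat shock genes had 2 of 36 higher and 2 lower (5 and 3 adjusted over the list alone; adjusted p = 0.929). Neither rise was kept without the infected library of 60.7 M, where HSP25, also named after its value was seen, went from 3.17 to 0.49, or without the uninfected ones of 6.55 M (3.29) and 8.76 M (3.09). Of the 2 falls 1, 0 and 1 were kept without these and 0 without the infected one of 4.25 M. No member was called by either adjustment among 14 B lymphocyte (adjusted p = 0.597), 15 T and NK lymphocyte (0.242), 21 pan-leukocyte (0.586), 14 thrombocyte (0.713), 24 erythroid (0.921), 37 neuron and glia (0.388) and 17 eye markers (0.875), 39 proliferation genes (0.953) and 5 W-linked genes (0.412). PTPRC was at 1.06 ± 0.51 (adjusted p = 0.277) and CD79B, part of the B cell receptor, at -3.17 ± 1.18 (adjusted p = 0.15, edgeR's quasi-likelihood test); neither passed.

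The 759 genes of day 7 became 252 and 378 without the uninfected libraries of 6.55 and 8.76 M counts, and the split moved to 195 higher and 545 lower without the infected library of 60.7 M and to 689 higher and 370 lower without that of 4.25 M. Without the infected library of 60.7 M and the uninfected ones of 6.55 and 8.76 M in turn, 36, 34 and 34 of the 39 interferon-stimulated rises kept their call. In virus sensing 9, 7 and 7 of 12 did, in interferon signalling 2 each of 5, and in antigen presentation 8, 6 and 5 of 13. Cell death kept 1, 1 and 2 of 4 rises, and cholesterol and fatty acid synthesis 1, 1 and 0 of 2. Complement and acute phase genes kept 2, 2 and 3 of 6 rises and 5, 2 and 3 of 5 falls. Glycolysis and hypoxia genes kept 1, 0 and 2 of 3 rises and 4, 2 and 2 of 4 falls. Of the 7 antimicrobial and granulocyte falls 7, 3 and 3 were kept without these, and 4 without the infected one of 4.25 M. DESeq2 called 1169 genes, and the 4 libraries of the day alone gave 64 (55 higher, 9 lower). Thinning to 2.78 M counts gave 502 (199 higher, 303 lower), 394 of them among the 759.

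**Figure D5:**
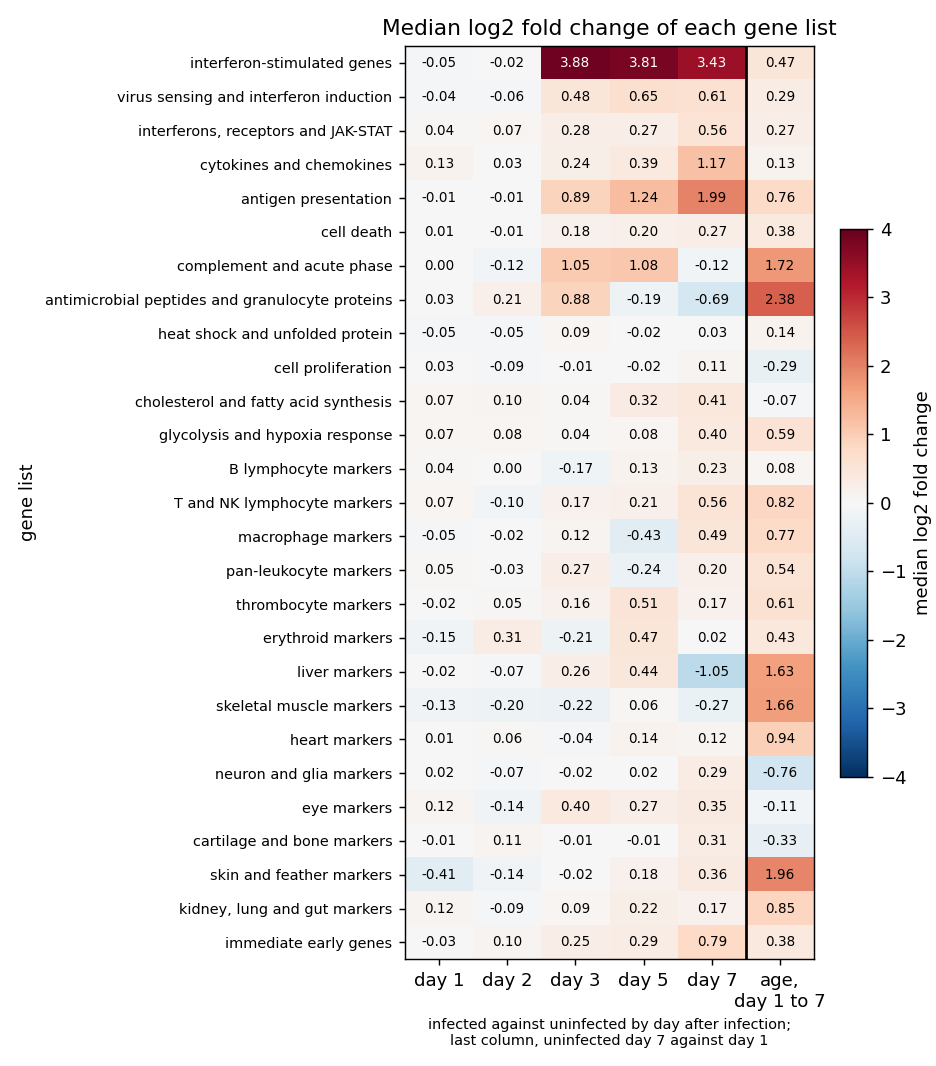
Median log2 fold change (colour and printed value) of each gene list (vertical axis) in infected against uninfected embryos on each day, with uninfected day 7 against day 1 in the last column; the W-linked list is not drawn. The interferon-stimulated list has medians of -0.05, -0.02, 3.88, 3.81 and 3.43, and the liver markers reach -1.05 at day 7.

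Averaged over the 5 days, 251 genes were higher and 66 lower in infected embryos. OASL rose by 5.57 ± 0.29 (adjusted p = 8.24e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), EPSTI1, an interferon-induced gene, by 4.73 ± 0.48, P2RX7, an ATP-gated channel of immune cells, by 3.91 ± 0.53 and PIT54, a haemoglobin-binding plasma protein of birds, by 3.15 ± 0.53. LY86 changed by -1.53 ± 0.19, HRG by -1.26 ± 0.14 and LIPC, hepatic lipase, by -1.07 ± 0.15. Of the 48 interferon-stimulated genes 36 rose (41 higher and 1 lower adjusted over the list alone; median 2.27, adjusted p = 6.29e-88 by camera, and adjusted p = 0.0131 with an estimated correlation). With an estimated correlation camera also placed higher virus sensing (11 of 28 rose, 14 adjusted over the list alone; adjusted p = 0.0304), interferon signalling (5 of 17 by both adjustments; 0.0304), antigen presentation (9 of 23, 14 adjusted over the list alone; 0.0304), cytokines and chemokines (0 of 23, 6 adjusted over the list alone; 0.0343), and cholesterol and fatty acid synthesis (1 of 32, 5 adjusted over the list alone; 0.0439). The 317 genes became 596 (446 higher, 150 lower) without the infected day 7 library of 4.25 M counts. The 66 lower genes became 195, beside 234 higher, without that of 60.7 M, and 122 without the infected day 3 library of 6 M. They became 38 to 42 without the infected libraries of 9.84 or 5.1 M (day 2), 2.78 M (day 3) or 10.04 M (day 5), or the uninfected ones of 6.71 M (day 1), 9.35 M (day 2), 5.96 M (day 3) or 7.34 M (day 5). DESeq2 called 550 (368 higher, 182 lower), thinning gave 173 (162 of them among the 317), and an average of days 3, 5 and 7 gave 789.

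The infection effect differed among the 5 days for 131 genes. The 10 smallest p values included 8 interferon-related genes, none of which passed at days 1 and 2 and all of which rose on days 3, 5 and 7. Of these IFIT5 had a ratio of 8.37 lower in infected embryos at day 2 (95% counting interval 2.57 to 43.2). OASL had log2 fold changes of 0.3, -0.47, 9.11, 9.66 and 9.23 on days 1, 2, 3, 5 and 7, and USP18, a brake on interferon signalling, -0.35, -0.01, 6.25, 6.06 and 5.92. S100A9 stood at 0.79, 1.39, 3.37, 1.33 and -0.46 (adjusted p = 0.000387 among days, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). BBOX1, the last enzyme of carnitine synthesis, stood at 0.12, 0.07, -0.06, -0.31 and -2.08 (adjusted p = 0.000386). Of the infected libraries, leaving out that of day 2 with 9.84 M counts gave 81 genes, that of day 5 with 6.58 M 87, and those of day 7 with 4.25 and 60.7 M 228 and 334. Of the uninfected libraries, leaving out that of day 1 with 6.71 M gave 83, those of day 2 with 9.35 and 6.12 M 83 and 85, that of day 5 with 8.02 M 87, and those of day 7 with 6.55 and 8.76 M 73 and 80, while DESeq2 called 397.

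The lists of genes higher on days 3, 5 and 7 overlapped. Days 3 and 5 shared 95 genes against 1.16 for independent lists (Fisher's exact test p = 1.65e-184), days 3 and 7 shared 105 against 2.91 (exact p = 3.12e-160) and days 5 and 7 shared 115 against 3.73 (exact p = 1.62e-159). A total of 89 genes were higher on all 3 days, 36 of them in the interferon-stimulated list. The falls of days 5 and 7 shared 10 genes against 0.456 (exact p = 3.53e-12), and 0 genes fell on all 3 days. The days share no libraries, but the spread of each gene was estimated over all 20 libraries. Genes that respond together are not independent, so the exact p values overstate the evidence.

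From day 1 to day 7 without infection 1339 genes rose and 1079 fell, as a scale for the infection effects. Age is not separate from sex here, since HNRPK stood at 118 and 148 CPM in the uninfected libraries of day 1 and at 8.7 and 0.228 CPM in those of day 7, and the W-linked list had a median of -4.27 (adjusted p = 0.126 by camera, and 0.515 with an estimated correlation). Genes placed on the sex chromosomes Z or W gave 66 of the rises and 22 of the falls. Their share among all genes tested was not computed. With W-linked expression as a covariate 1621 genes were called (915 higher, 706 lower), 809 of the 1339 rises and 641 of the 1079 falls among them. Medians were 1.44 and -1.12 (median SEs 0.33 and 0.26) without the covariate. They were 1.42 and -1.11 (0.38 and 0.3) with it. The slope of the covariate came mostly from infected pairs, so this does not set age apart from sex. AHSG (fetuin), a major plasma protein of the embryo, rose by 11.52 ± 2.07, and the keratin KRT23 was at least 42.1-fold higher. HOXD12, which patterns the limb, was at least 107-fold lower. The embryonic globins HBZ (-6.9 ± 0.86, adjusted p = 0.000446, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and HBG1 (-6.47 ± 0.87) fell. Skeletal muscle markers rose in 22 of 34 (24 adjusted over the list alone; median 1.66, adjusted p = 1.53e-10 by camera, and 0.515 with an estimated correlation), with MYH1C, a fast myosin, at 5.25 ± 0.62 and ACTA1 at 2.97 ± 0.4. Skin and feather markers had 16 of 32 higher and 1 lower (19 and 1 adjusted over the list alone; median 1.96, adjusted p = 6.34e-07, and 0.515 with an estimated correlation), with TGM3 at 5.4 ± 0.9. Antimicrobial and granulocyte genes had 11 of 25 higher (14 adjusted over the list alone; median 2.38, adjusted p = 6.9e-07, and 0.515 with an estimated correlation), with LECT2 at 4.24 ± 0.71 and S100A9 at 3.35 ± 0.26. Complement and acute phase genes had 13 of 35 higher and 2 lower (24 and 2 adjusted over the list alone; median 1.72, adjusted p = 2.7e-06, and 0.515 with an estimated correlation), with C8B at 4.37.

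With age, liver markers had 13 of 39 higher (21 adjusted over the list alone; median 1.63, adjusted p = 2.46e-06, and 0.515 with an estimated correlation). ALB, serum albumin, rose by 3.97 ± 0.91 from 3140 ± 1080 to 49400 ± 9780 CPM, a call lost without the uninfected day 1 libraries of 6.71 (4.38) and 6.65 M counts (3.66). Neuron and glia markers split, with 3 of 37 higher and 10 lower (5 and 13 adjusted over the list alone; median -0.76, adjusted p = 0.0019, and 0.515 with an estimated correlation). MBP, a myelin protein, rose by 3.12 ± 0.52, and NEFM, a neurofilament, changed by -1.69. Heart markers had 9 of 22 higher and 1 lower (11 and 2 adjusted over the list alone; adjusted p = 0.00404), macrophage markers 7 of 27 higher (8; 0.00404), and glycolysis and hypoxia genes 7 of 31 higher and 1 lower (9 and 1; 0.00431), each at 0.515 with an estimated correlation. Proliferation genes had 2 of 39 lower (2 adjusted over the list alone; median -0.29, adjusted p = 0.00347, and 0.515 with an estimated correlation). Interferon-stimulated genes had 5 of 48 higher (2 adjusted over the list alone; median 0.47, adjusted p = 0.027, and 0.609 with an estimated correlation). Antigen presentation (3 of 23 higher, 2 adjusted over the list alone; adjusted p = 0.0125), kidney, lung and gut markers (8 of 33 higher and 1 lower by both adjustments; 0.0436) and immediate early genes (4 of 22 higher by both; 0.0416) also passed, while cartilage and bone markers did not (4 of 37 higher and 7 lower, 5 and 9 adjusted over the list alone; 0.223). With an estimated correlation none of the lists passed in this comparison (smallest adjusted p = 0.515). The 2418 genes became 1106 and 827 without the uninfected day 1 libraries of 6.71 and 6.65 M counts and 1318 and 1270 without the day 7 libraries of 6.55 and 8.76 M, and thinning to 2.78 M counts gave 1015. Without these 4 libraries in the same order, 19, 13, 21 and 15 of the 22 skeletal muscle rises kept their call. In skin and feather 7, 7, 5 and 14 of 16 did, and in antimicrobial and granulocyte genes 5, 3, 8 and 5 of 11. Complement and acute phase kept 4, 2, 6 and 7 of 13 rises, liver 2, 1, 2 and 4 of 13, and heart 5, 1, 6 and 5 of 9. Macrophage markers kept 1, 2, 2 and 3 of 7 and interferon-stimulated genes 0, 0, 1 and 1 of 5. Of the 10 neuron and glia falls 5, 7, 8 and 4 were kept.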

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

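The tests of the differences between pairs of days, of signs on another day, of the W-linked covariate, of thinning, of the change of the interferon-stimulated genes with age, and of liver markers were chosen only after the results were seen. The reassignments of libraries, the comparison with leukocyte markers, the correlations with age, and the W-linked differences and ratios of library totals on each day were planned.

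The infection effect differed among the 5 days for 131 genes, by an F test of the differences themselves. The 10 with the smallest adjusted p (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) were OASL (5.71e-05), ZNFX1, HELZ2, USP18 and RNF213 (8.41e-05 each), IRF7 (0.000169), IFIT5 (0.000293), BBOX1 (0.000386), and IFIH1 and S100A9 (0.000387 each). The count fell to 73 without the uninfected day 7 library of 6.55 M counts and rose to 334 without the infected day 7 library of 60.7 M. Between day 5 and day 7 the effect differed for 34 genes, 32 of them lower at day 7, among them HRG (difference of log2 fold changes -4.57 ± 0.46, adjusted p = 0.000862), SERPINA4 (-4.25), SPP2 (-3.85), LDHB (-2.42) and BBOX1 (-1.76 ± 0.22, adjusted p = 0.00785). Between day 3 and day 7 it differed for 13 genes, all lower at day 7, among them AvBD1 (-6.63), LECT2 (-5.97), HRG (-4.27) and S100A9 (-3.83 ± 0.34, adjusted p = 0.000169). Between day 3 and day 5 edgeR called 0 genes. An unadjusted p under 0.05 was seen for 557 of 15122 genes, below the share of 0.05 that no difference would give. The spread shared by all groups may be too large for these days, so this does not show equal effects. DESeq2 was not run on differences between pairs of days. Of 84 list tests between pairs of days, 17 passed at the preset correlation of camera and 0 with an estimated one. Liver markers were lower at day 7 than at day 5 by a median of -1.99 (adjusted p = 2.82e-19, and adjusted p = 0.611 with an estimated correlation).

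The interferon-stimulated genes were higher as a list on days 3, 5 and 7. More leukocytes in the infected embryos, with their own expression unchanged, would raise leukocyte markers as much. Leukocytes that themselves raised these genes are not covered by this comparison. The median of the list exceeded that of the pan-leukocyte markers by 3.61 ± 0.43, 4.05 ± 0.37 and 3.23 ± 0.35 (log2) on days 3, 5 and 7. These errors, and those for age below, come from resampling genes, which are not independent, and leave out the spread between libraries. The sex of the embryos is argued against, since all 38 members called higher at day 3 were above 0 at day 5. There the W-linked difference had the other sign. The 95% binomial interval of 90.7 to 100% takes genes as independent, which they are not. An older stage is argued against by the change of the list with age, a median of 0.47 from day 1 to day 7 (where W-linked HNRPK went down too), below the infection effect by 3.41 ± 0.43, 3.34 ± 0.38 and 2.96 ± 0.36. These explanations are argued against, that of leukocytes only for ones with unchanged expression. A response of the embryos to the virus remains as a hypothesis, found and tested on the same data. How many embryos a library holds stays open.

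More genes were called at day 7 (759) than at days 3 (118) and 5 (168), and embryo stage, sex and library size were weighed. The order is not kept with only the libraries of each day, which gave 64, 137 and 229 genes on days 7, 3 and 5. A difference in stage would line up the changes of the called genes with age in other uninfected libraries. The correlation across these genes, which are not independent, was 0.05 at day 3, 0.13 at day 5 and -0.04 at day 7. At day 3 it ran from -0.19 to 0.23 with 1 library left out, and was 0.29 outside the interferon-stimulated list. This test covers called genes only. On the first principal component uninfected libraries went from -45.2 and -53.2 at day 1 to 82.3 and 70.1 at day 7. There infected libraries stood at 70.6 and 27.5 at day 5, against 33 and -0.2 in uninfected ones. Infected libraries had -8.5 and -14.8 against -9.2 and -38 at day 3, and 73.6 and 92.4 at day 7. A stage difference at day 5 therefore stays open. The planned test for sex came out as sex would have it on days 3 and 5, where W-linked HNRPK differed between the groups in each pair of libraries by at least 6.46 and at most -7.13 on the log2 scale; at day 7 the pairs ran from -3.24 to 7.73. These differences show that sex is unequal, not that it made the calls. Genes placed on the sex chromosomes Z or W gave 9 of the 376 rises and 29 of the 383 falls at day 7. They gave 3 of 117 rises at day 3 and 8 of 150 at day 5, with 0 falls. The share of such genes among all genes tested was not computed, so these counts show neither an excess nor a lack. A part played by sex in the day 7 calls stays open. Against sex as the whole cause, 117 of 117 genes higher at day 3 had the same sign at day 5. Of those higher at day 5, 144 of 150 had the same sign at day 3 (95% binomial interval 91.5 to 98.5%). Of those lower at day 5, 14 of 18 did (52.4 to 93.6%). The intervals take genes as independent, which those that respond together are not. With W-linked expression as a covariate 68 of 118, 97 of 168 and 566 of 759 calls stayed on days 3, 5 and 7. The rises had medians of 3.31, 3.03 and 1.66 without it and 3.16, 3.23 and 1.55 with it, all with the same sign. Median SEs were 0.46, 0.44 and 0.35 without it and 0.55, 0.56 and 0.36 with it. The slope of the covariate comes only from groups whose 2 libraries differ in HNRPK, mainly the infected pairs of days 1, 2 and 7. On days 3 and 5 HNRPK was close within each group and far apart between the groups. Folds that changed little there rest on a slope from other days and do not decide on sex. Of the 18 falls of day 5 only 3 stayed; all 18 were still below 0, and their median went from -1.47 (median SE 0.32) to -1.22 (median SE 0.39), so the calls ended with a smaller fold and a wider error, and a part played by sex in these falls stays open. The planned test for library size came out as size would have it, since the day with most calls had a ratio of mean totals of 4.24, infected to uninfected, against 0.763 to 1.08 on the other days. Against size as the whole cause, day 7 still gave 502 calls with every library thinned to 2.78 M counts, against 88 at day 5 and 95 at day 3. The infected pair of day 7 was the least alike (correlation 0.912, against 0.953 to 0.971 in the other groups) and differed most in total (ratio 14.28). The spread used for its test was shared by all groups and may be too small for this pair. That, a response that differs at day 7, or a difference in the handling of single libraries remains open and was not tested.

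Of 39 liver markers 11 fell at day 7 and 28 did not pass (list median -1.05, adjusted p = 2.48e-12 by camera, and adjusted p = 0.554 with an estimated correlation), and an earlier stage, a smaller share of liver RNA and a single library were weighed. An earlier stage of the infected embryos predicts muscle and skin medians of -2.01 and -2.43, while -0.27 and 0.36 were seen. The smaller excess was thus 1.74 ± 0.85 and the other 2.78 ± 1.1. Errors of the excesses come from resampling genes and leave out the spread between libraries. The prediction scales with the liver median and depends on the libraries kept. Without the infected library of 4.25 M counts the muscle and skin excesses were 0.63 ± 0.75 and 1.12 ± 0.97, without that of 60.7 M 7.37 ± 1.85 and 9.9 ± 2.44, and the muscle excess was also within 2 SE without the uninfected libraries of 6.55 M at day 7 (1.85 ± 1.08) and 8.02 M at day 5 (1.21 ± 0.73). An earlier stage therefore cannot be told apart from an infection effect, because the infected libraries differ. A smaller share of liver RNA in both infected libraries, as the whole cause, would lower all liver markers in both. Against the uninfected mean, 36 markers ran from -3.13 to 2.77 in the library of 60.7 M counts, but from -7.36 to -0.06 in that of 4.25 M. Only the library of 60.7 M therefore argues against it, and a smaller share in that of 4.25 M stays open. Of the 11 called markers 10 were still lower with either infected library left out, but they had been picked as lower over both, so this decides nothing. A single infected library cannot be told apart from an infection effect, for these markers or for the list as a whole. Without the library of 60.7 M 29 markers were lower and 0 higher (median -3.93), while without that of 4.25 M 11 were lower and 7 higher, and the median of -0.6 did not pass with an estimated correlation (adjusted p = 0.786).

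For the average over the 5 days, libraries were reassigned between the groups within each day 100 times, the real grouping included, and 1 of these, the real one with 317 genes, gave as many. The real grouping thus ranked first of the 100, but a count of calls does not by itself exclude chance or set infection apart from other structure. The margin is narrow. The highest other count was 311, from a reassignment that exchanged 1 library of each group on a single day and shared 276 genes with the real one. The next was 305, with libraries exchanged on 4 of the 5 days and 20 genes shared, which points to a structure among the libraries apart from infection that was not traced. The third highest was 38, and the median of the others was 0.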

How the results depend on the processing

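The covariate for W-linked expression, thinning and the average of days 3, 5 and 7 were chosen after seeing the data; the other settings were planned. Where a call was lost, the cause was not tested unless stated. Median-of-ratios scaling gave 117, 168, 758, 319, 130 and 2411 genes for days 3, 5 and 7, the average, the test among days and the change with age, and no low-count filter gave 142, 183, 796, 360, 182 and 2361, all within 1.5 times the reported counts. DESeq2 called 2, 1, 187, 283 and 1169 genes on days 1, 2, 3, 5 and 7, 550 for the average and 397 among days. With only the 4 libraries of the day, which leaves 2 residual degrees of freedom, days 3, 5 and 7 gave 137, 229 and 64 genes, so that day 7 had the fewest of the 3. W-linked expression as a covariate gave 68 genes at day 3, 108 at day 5, 86 among days and 1621 with age, with the medians of the rises of days 3 and 5 at 3.16 and 3.23 against 3.31 and 3.03 and wider errors. Thinning to 2.78 M counts, which removes counts by construction, gave 88 genes at day 5, 502 at day 7, 173 for the average and 1015 with age. The average of days 3, 5 and 7 gave 789 genes.

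Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the others, gave 55 to 194 genes at day 3, 61 to 113 at day 5, 252 to 1059 at day 7, 223 to 596 for the average, 73 to 334 among days and 827 to 1318 with age; days 1 and 2 stayed at 0. The interferon-stimulated list ranged from -0.16 to 0.03 at day 1, where it was 0 without the uninfected library of 6.71 M counts and 0.03 without the infected one of 9.6 M. It ranged from -0.18 to 0.17 at day 2, with 0.17 without the uninfected library of 9.35 M and -0.17 without that of 6.12 M, where it passed (adjusted p = 0.0387 by camera). Its medians of 2.84 to 4.63 at day 3, 3.61 to 3.94 at day 5 and 3.27 to 3.61 at day 7 all passed by camera at the preset correlation. Without the infected day 7 library of 60.7 M counts SPP1 went to -0.13, HPX to -3.56, PCK1 to -0.72 and ORM1 to -0.6, the lowest of ranges that reached 3.97, 2.72, 2.33 and 3.6 without that of 4.25 M. In the change with age TAL1 ranged from -0.09 without the uninfected day 7 library of 8.76 M to 1.8 without that of 6.55 M. Of the named genes past the threshold, 21 of 34 at day 3, 22 of 47 at day 5, 46 of 74 at day 7, 41 of 58 for the average and 42 of 104 with age kept their call with each library left out in turn. No paired analysis was possible by replicate number because the columns carry no replicate numbers. The planned fits with a replicate block were therefore not run. The columns hold the 10 groups 2 times in the same order, but a block by that order was not fitted either. The earlier column stood higher on the first principal component in each group except infected day 7 (73.6 against 92.4). At day 5 the values were 70.6 against 27.5 in infected and 33 against -0.2 in uninfected embryos. An offset between the 2 sets of columns stays open and was not tested. Depth limits the low counts: at 2.78 M counts a gene at 1 CPM has about 3 counts in the smallest library.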

Other observations

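The tests reported in this part were all among those already described, and the genes of the day 7 libraries below were chosen only after the result was seen. Single libraries of day 7 differed in some liver and acute phase genes. SAAL1 of the complement and acute phase list did not (49.2 and 64.4 CPM in infected against 58.7 and 61.3 in uninfected libraries). With age, however, SAAL1 was 1 of 2 members of that list called lower while 13 rose, so it does not stand for the others. HPX (haemopexin), which binds haem in plasma, stood at 202 CPM in the infected library of 60.7 M counts and 2.59 CPM in that of 4.25 M, against 41.3 and 20.8 CPM in the uninfected libraries. ORM1, an acute phase glycoprotein, stood at 917 and 50.2 CPM against 82.9 and 69.7, and PCK1, an enzyme of glucose synthesis, at 434 and 52.8 CPM against 84.3 and 89.6. None of the 3 genes passed over both infected libraries (log2 fold changes 1.76, 2.67 and 1.5). ALB fell by 4.02 (adjusted p = 0.0192, edgeR's quasi-likelihood test), from 56300 and 42500 CPM to 5580 and 501, missed the threshold without the uninfected library of 6.55 M (-3.78), and was at -6.62 without the infected one of 60.7 M. C1S, by contrast, was higher in both infected libraries, at 309 and 218 CPM against 24.9 and 20.4.

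EPSTI1, DDX60 and CMPK2, all induced by interferon, rose at day 7 by 8.01 ± 0.69, 6.06 and 6.32 on the log2 scale, and AVD rose by 7.02 ± 0.89. SAMD9L, an interferon-induced antiviral factor, was at least 62.7-fold higher at day 7, where it kept its call with each library left out. INDOL1, a tryptophan-degrading enzyme, fell by 5.27 (SE 0.62) at day 7, IL20RA, a cytokine receptor chain, by 4.11 (SE 0.48) and PFKFB4, a regulator of glycolysis, by 3.3 (SE 0.5).

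The uninfected day 7 library of 6.55 M counts had a W-linked level between those of the other libraries, with HNRPK at 8.7 CPM and UBE2R2L at 1.68 CPM.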
